A study of Arabidopsis thaliana with 6 samples.

How the data were processed

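Total RNA of whole seedlings aged 15 days was measured on 6 one-colour Affymetrix arrays, 3 of wild type and 3 of gapcp1gapcp2. Groups were taken from the sample titles, which also number the biological replicates. The samples' description fields speak of embryo stages, which no other label of the samples shares, and they were not used. Per the labels' protocols, plants grew vertically on dilute medium in long days, RNA was prepared from 3 sets of each genotype, raised together, and biotin-labelled cRNA was hybridised.

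The authors deposited a table of intensity values per probe set and array on a linear scale. It holds 22746 probe sets, no control probe sets and no detection calls. GCOS is the only tool that the submitters' processing notes name, and its version and the scaling are not given in the sources used here. Values below 0 occur (1.85% of values), and the median intensity was 114, 116 and 113 in wild type replicates 1 to 3 and 110.7, 117 and 117 in the mutant replicates. The authors also deposited a comparison table of 274 probe sets with their group mean intensity, signed fold change, bounds, difference of means, t statistic and p-value. Per the file headers, that table was filtered on a fold change over 2, a difference over 100 and a p of at most 0.05, with averaging by standard errors, and its array numbers go up to 12. The authors' fold change score is written negative where the mutant is lower. A second comparison file holds the same 274 probe sets with equal values and was not used otherwise. In the deposited table the t statistic score lost its decimal comma, so it is 1000 times that of the second file, and it was not used. Of the sources used here, only the authors' deposited table pairs a probe set with a locus, and 273 of 274 loci were found in the RefSeq table of TAIR10.1 names. A probe set shared between transcripts (18 of 274) was not named.

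Values below 0 were set to 0 and log2(intensity + 16) was taken, with no further normalisation because array medians were nearly equal. A fold change on this scale understates the change of dim probe sets. Each probe set was tested with limma 3.58.1 (lmFit and eBayes, two-sided, R 4.3.3) on all 6 arrays without a block, with Benjamini-Hochberg adjustment over 22746 probe sets and an adjusted p under 0.05. The depth of an array is not a count, so the 3 arrays per group set the precision. Setting values below 0 to 0 was not in the planned design and was chosen once the files were seen.

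The design also planned set tests (camera and fry) and counts adjusted over the list alone. These were left out, because list members could be named here only where the authors' filter selected them, and such tests on selected members would be void. Instead, after the files were seen, a one-sided exact hypergeometric test was run for each of 29 gene lists fixed before the data were examined, with Benjamini-Hochberg adjustment over the 29. It set the 256 table probe sets of 1 locus against 12092 probe sets of 1 locus whose brighter group mean exceeded 100, and it assumed that each list member is among these 12092. Of 492 list entries, 484 matched a RefSeq name and 8 were left out. Of 2000 random lists of 20 members, 1% had a p under 0.05. The test treats genes as independent draws, and so do the random lists. Members of a list can change together on the same arrays, so its p-values can be too small and do not measure replication.

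Genes named in the text follow a rule fixed before the data were examined: members of the glyceraldehyde-3-phosphate dehydrogenase family list, the 12 highest and 12 lowest log2 changes among called probe sets of 1 gene with non-overlapping arrays and a brighter group mean log2 at or above the median, and up to 4 passing members of each list with the largest changes. Other list members and other genes are named after their values were seen. The limma steps were tested on simulated data for the 22746 probe sets with 200 changed. The changed ones were drawn from probe sets with a wild-type mean at or above the median, with independent noise. The recovery below therefore does not cover probe sets dim in wild type, such as that of IRT1, or deviations shared by a whole array. At 1.5-fold, 59.7% of changed probe sets were recovered, at 2-fold 94.0% and at 4-fold 100%, with 3.43% false calls. With no change simulated, 0 probe sets were called.

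Alternatives were quantile normalisation, median centring, leaving out the dimmest 40% or 60% of probe sets, trend and robust moderation, no moderation, pseudocounts of 1 and 64, a 2-fold threshold, the replicate number as a block, array weights and leaving out each array. Added after the data were seen were leaving out shared probe sets, leaving out both arrays numbered 1, a block for those arrays, other backgrounds and list sizes for the enrichment test, and list entries taken by locus without a name match. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for lists, Fisher's exact tests and plots. No genome coordinates were used.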

Results

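The data were 6 microarrays of *Arabidopsis thaliana*, ecotype Col-0. Each array measured RNA of whole seedlings aged 15 days. The seedlings were either wild type (3 biological replicates) or the double mutant gapcp1gapcp2 (3 biological replicates). GAPCp is the plastidial, glycolytic form of glyceraldehyde-3-phosphate dehydrogenase, the enzyme that oxidises glyceraldehyde 3-phosphate in glycolysis. Its paralogues GAPCP1 and GAPCP2 are the genes named in the mutant. Each array gave an intensity for 22746 probe sets, and the median intensity per array lay between 110.7 and 117.1. The number of arrays, 3 per group, limits the precision of each value. The comparison asked which transcripts differ in abundance between seedlings with and without both genes.

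Of the 29 gene lists, those of the iron deficiency and phosphate starvation responses had the most members in the authors' deposited table. Only probe sets in that table could be named. The iron transporter gene IRT1 was brighter in the mutant, with a log2 change of 3.99 that depends on the pseudocount (2.95 at 64, 4.65 at 1), and 3 ferritin genes, which encode iron storage proteins, were dimmer. All 8 phosphate starvation genes that could be named were brighter. On the log2(intensity + 16) scale the named transcript with the lowest change was CYP712A1, a cytochrome P450 gene, which went from an intensity of 424 ± 56.6 to 23.9 ± 3.93 (SD, n = 3 each), and its log2 change depends on the pseudocount (-2.47 at 64, -4.10 at 1).

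Between the genotypes, 2501 of 22746 probe sets passed the limma test at an adjusted p under 0.05, with 1334 higher and 1167 lower in gapcp1gapcp2. Of these, 390 also differed by at least 2-fold on the log2(intensity + 16) scale, with 222 higher and 168 lower. The mutant and wild-type arrays did not overlap for 7295 probe sets (32.1%), and chance gives 10% for 3 arrays against 3. The count of calls was sensitive to single arrays. It was 1422 without wild type replicate 2, 1190 without mutant replicate 2 and 1197 without mutant replicate 3.

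With the sources used here, a probe set could be tied to a gene only where the authors' deposited table pairs them, which it does for 274 probe sets. The authors' deposited table holds probe sets past a filter on fold, difference and p. Its array numbers go up to 12 and 50 of its 274 probe sets have a group mean outside the range of the arrays used here, so whether it rests on these 6 arrays alone is unknown. Its genes are not treated as independent evidence of change. All 274 passed the limma test here in the direction that the authors' deposited table gives, and the arrays of the 2 genotypes did not overlap for any of them. Of these, 256 belong to 1 locus each (157 higher, 99 lower) and 18 are shared between transcripts and were not named. No probe set of GAPCP1 or GAPCP2, or of the other 6 members of the glyceraldehyde-3-phosphate dehydrogenase list, was named. The targeted transcripts therefore could not be used to check the genotype labels.

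Of the 12 members of the list for the iron deficiency response and ferritins, 9 were in the authors' deposited table. Of these 6 were higher in the mutant and 3 were lower. This is more than independent draws give among probe sets of sufficient intensity (0.254 members expected, one-sided exact hypergeometric test, adjusted p = 4.5e-12 over 29 lists). Genes of this response can change together, so this p can be too small. IRT1, the main root iron uptake transporter, rose from 23.3 ± 2.04 to 617 ± 114 (log2 change 3.99 ± 0.14 SE, limma adjusted p = 8.7e-05). The transcription factor genes BHLH101 and bHLH39 rose by 3.55 ± 0.24 and 2.64 ± 0.11 on the log2 scale (bHLH39 by 1.99 at a pseudocount of 64 and 2.97 at 1). The wild-type intensity of BHLH101 was close to 0 (10.1 ± 9.55), so its size of change depends on the pseudocount and ranged from 2.22 to 4.99 over the alternatives. FER1, a ferritin gene, fell from 3112 ± 221 to 863 ± 119 (log2 change -1.84 ± 0.12 SE, limma adjusted p = 0.00052). The other members in the table were FRO3, OPT3 and NAS4, which were higher, and the ferritin genes FER3 and FER4, which were lower. The root cell markers CASP1 and TIP2;3 were lower on the same mutant arrays (log2 changes -1.50 and -1.57). The 3 iron list members without a named probe set have unknown values here.

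**Figure D1:**
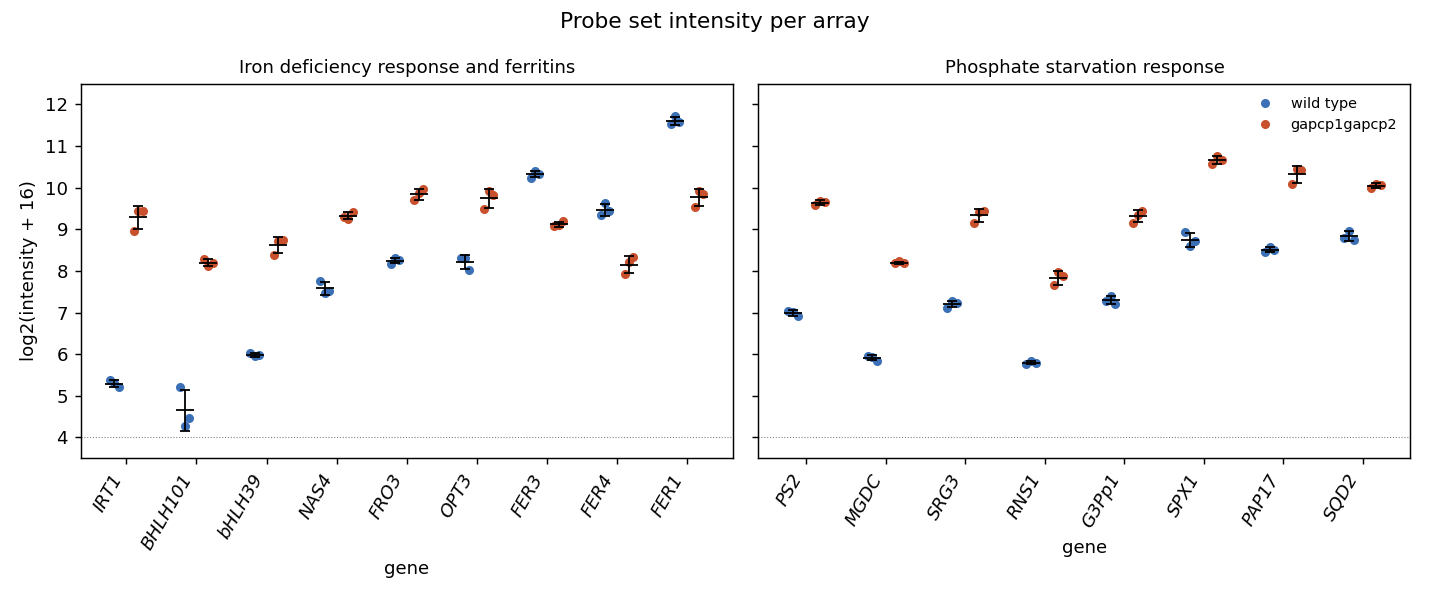
Intensity on a log2 scale, as log2(intensity + 16) after values below 0 were set to 0, for named members of the iron (left) and phosphate (right) lists. Points are single arrays of wild type and gapcp1gapcp2 (3 each), bars are the mean and SD, and the dotted line marks an intensity of 0. The wild-type and mutant points do not overlap for any gene shown, and FER1, FER3 and FER4 are the genes that are lower in the mutant.

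Of the 14 countable members of the phosphate starvation list, 8 were in the authors' deposited table, and all 8 were higher in the mutant (0.296 expected, one-sided exact hypergeometric test, adjusted p = 1.4e-09). PS2, a phosphatase gene induced by low phosphate, rose from 111 ± 5.51 to 784 ± 28.5 (log2 change 2.65 ± 0.07 SE, limma adjusted p = 6.3e-05). MGDC, which makes galactolipids that replace phospholipids when phosphate is low, rose from 44.4 ± 2.54 to 277 ± 5.44 (log2 change 2.28 ± 0.06 SE). SRG3 and RNS1, which encode a glycerophosphodiester phosphodiesterase and a ribonuclease, rose by 2.13 ± 0.10 and 2.04 ± 0.10 on the log2 scale. The folds of MGDC and RNS1, dim in wild type, moved by over 1.5 times with a pseudocount of 1 or 64. SPX1, SQD2, PAP17 and G3Pp1 were the other counted members that rose. A further member lay on a probe set shared between transcripts and was left out of the count. That probe set was in the table and higher (log2 change 1.51). The root markers CASP1 and TIP2;3 fell on these arrays too.

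The sulfate list had 4 of 24 members in the table (0.508 expected, one-sided exact hypergeometric test, adjusted p = 0.014). LSU1, LSU2 and ATSDI1, known as transcripts that accumulate in sulfur-deprived plants, were higher. LSU1 went from 149 ± 14.4 to 1184 ± 13 (log2 change 2.87 ± 0.08 SE). APS4, an ATP sulfurylase gene that acts in sulfate assimilation, was lower (log2 change -1.29 ± 0.06 SE). The abscisic acid list had 4 of 30 members in the table, all higher (0.635 expected, adjusted p = 0.025 by the same test). The root markers CASP1 and TIP2;3 (log2 changes -1.50 and -1.57) fell on the same mutant arrays as the sulfate and abscisic acid list changes. COR15A, which encodes a chloroplast protein that protects membranes in cold, rose from 661 ± 22.5 to 2711 ± 66.4 (log2 change 2.01 ± 0.06 SE), and COR15B and RD20 rose by 1.18 ± 0.10 and 1.11 ± 0.11 on the log2 scale. GolS2, a galactinol synthase gene, had a mean of -16.2 ± 2.59 in wild type, which lies below 0, and 109 ± 10.9 in the mutant, so no fold is given for it.

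In 10 further lists the members in the table were few, and none of these lists passed the enrichment test. The salicylic acid and pathogen list had 3 of 21 members, BGL2, PR5 and WRKY54, all higher (adjusted p = 0.052 by the exact hypergeometric test). The anthocyanin list had 3 of 22 members, DFR, UF3GT and GSTF12, all higher (adjusted p = 0.052). A further entry of this list, AT4G14090 (UGT75C1), was left out because its written name did not match the reference table, and it was higher too (log2 change 1.68 ± 0.08 SE). With entries taken by locus, an alternative chosen after the data were seen, the anthocyanin list had 4 of 23 members and passed (adjusted p = 0.011). The salicylic acid list passed as well (adjusted p = 0.045), but its counts and unadjusted p did not change. Only its rank in the adjustment over the lists did. Both passed with a background of all probe sets of 1 locus (adjusted p = 0.010 each), a setting that can only lower the p of a list. The jasmonate list had 2 of 18 members, LOX2 and CORI3, both higher (adjusted p = 0.23), and LOX2 rose from 1769 ± 62.1 to 4991 ± 114. In this list 2 further members lay on probe sets shared between transcripts and were left out of the count. Both probe sets were in the table and higher (log2 changes 1.38 and 1.08), and the enrichment test was not run with them. The starch list had 2 of 24 members, GBSS1 and APL3, both higher (adjusted p = 0.29). The root cell marker list had 2 of 22 members, CASP1 of the endodermis and the tonoplast channel TIP2;3, both lower (log2 changes -1.50 ± 0.08 and -1.57 ± 0.08 SE, adjusted p = 0.28). The other lists each had 1 member. GPT2, the plastid glucose 6-phosphate transporter, rose by 1.76 ± 0.09 (adjusted p of its list 0.77), SAG29 of leaf senescence rose by 1.51 ± 0.14 (0.55), and the nitrate transporter NRT2:1 rose by 2.16 ± 0.08 (0.78). ERD5, a proline dehydrogenase gene, fell by 1.09 (SE 0.10, adjusted p of its list 0.29), and SEN1 of the sugar starvation list fell by 1.16 (SE 0.11, 0.78).

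**Figure D2:**
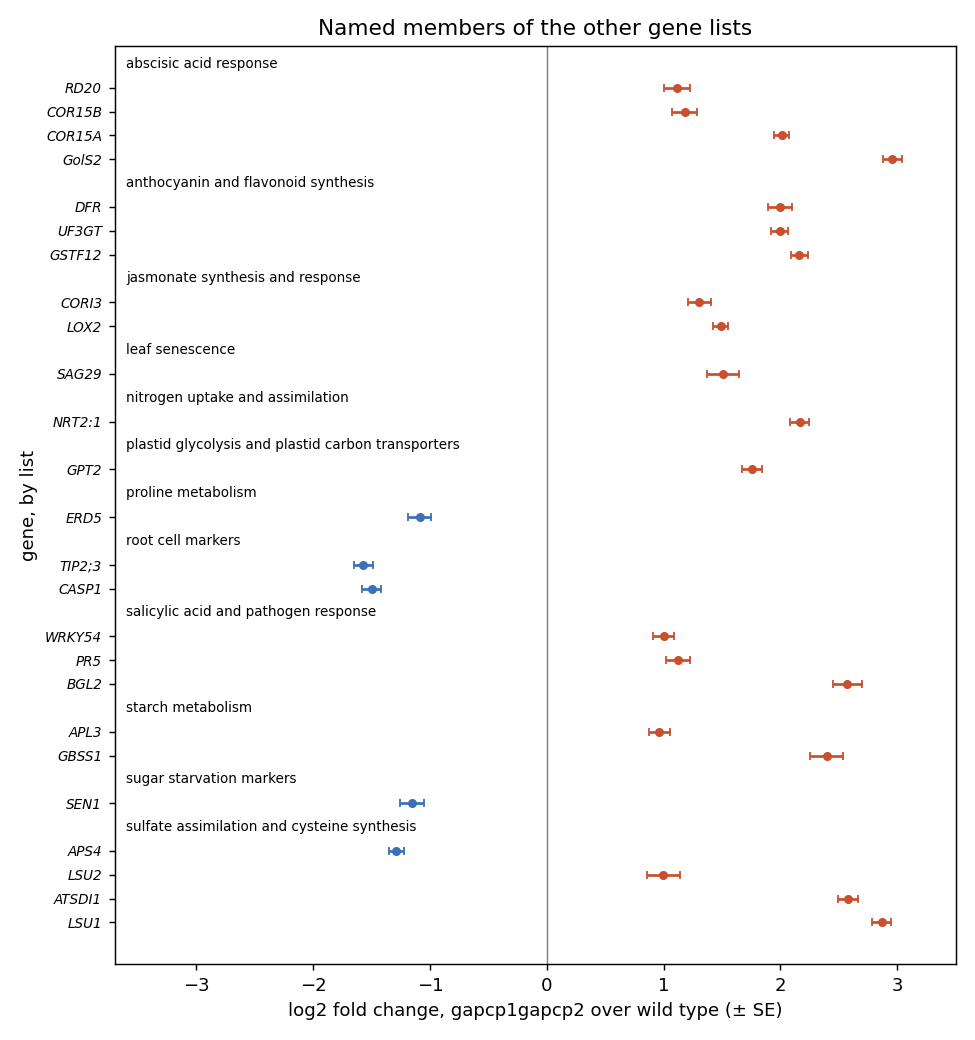
Log2 change of gapcp1gapcp2 over wild type, with bars for the SE of the limma fit (3 arrays per group), for the named members of the lists other than iron and phosphate. Red points are genes higher in the mutant and blue points genes lower. LSU1 (2.87) and GolS2 (floored in wild type) lie farthest to the right. The position and SE of GolS2 depend on that floor and on the pseudocount, so they are no estimate of its fold.

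The other 15 lists had no member in the table. They cover the glyceraldehyde-3-phosphate dehydrogenase family, the phosphorylated serine pathway, photorespiration, photosystems, the Calvin cycle, cytosolic glycolysis, the tricarboxylic acid cycle, plastid fatty acid synthesis, tryptophan synthesis, glucosinolate synthesis, cell division, seed storage, flowering, the clock, and heat shock with oxidative stress. Their probe sets were not named here, so their values are unknown and no absence of change is stated.

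Besides list members, the genes with the highest log2 changes were AT1G47400, an iron-deficiency peptide gene, which went from 65.4 ± 12.2 to 1452 ± 27.9 (log2 change 4.18 ± 0.11 SE), and CYP82C4, a cytochrome P450 gene, from 7.21 ± 0.766 to 317 ± 59 (log2 change 3.83 ± 0.14 SE). The wild-type intensity of CYP82C4 is close to 0, so the ratio depends on the pseudocount. AT1G80130, the thioredoxin gene TH8, the MATE efflux gene AT2G04050 and the oxygenase gene AT3G12900 rose by 2.85 to 3.23 on the log2 scale. The wild-type intensities of AT2G04050 (13.8 ± 12.6) and AT3G12900 (10.2 ± 14) were close to 0 too, and AT3G12900 no longer passed at a pseudocount of 1 (limma adjusted p = 0.077). AT5G04120, of the phosphoglycerate mutase family, rose from 20.1 ± 3.1 to 268 ± 22.4 (log2 change 2.98 ± 0.10 SE, and 1.98 at a pseudocount of 64 and 3.68 at 1). The folds of AT1G47400, AT1G80130 and TH8 also moved by over 1.5 times with a pseudocount of 1 or 64. At a pseudocount of 1 the order of the highest turned, with CYP82C4 at 5.26 and AT3G12900 at 4.81 above AT1G47400 at 4.47. The lowest log2 changes were those of CYP712A1 (-3.46 ± 0.12 SE), the dioxygenase gene AT1G52820 (-3.28 ± 0.06), AT3G06390 (-2.41 ± 0.10) and the arabinogalactan protein gene AGP30 (-2.32 ± 0.18). Their mutant intensities were low (13.0 for AT1G52820 and 23.9 for CYP712A1), so their folds, and that of CYP78A8, moved by over 1.5 times with a pseudocount of 1 or 64, and the order turned, with AT1G52820 at -4.25 and CYP712A1 at -4.10 at a pseudocount of 1. AT3G25190, AT2G37750, the major latex protein gene MLP329, the pectinesterase gene AT2G45220, MEE3, AT4G22212, AGP13 and CYP78A8 followed, with log2 changes between -2.18 and -1.94. In all, 2227 called probe sets lay outside the table and were not named. Of these, 1 had a log2 change above the lowest of the 12 highest named, and 3 had a log2 change below the highest of the 12 lowest named.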

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

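Leaving out both arrays numbered 1, the block for those arrays, leaving out shared probe sets, the other enrichment backgrounds and taking list entries by locus were chosen after the data were seen. Of 1012 alternative values of the 52 named genes, 1009 stayed past the threshold in the same direction and 0 reversed. These genes come from the authors' filtered table, so this says nothing about other genes. The exceptions were APL3 and LSU2, whose log2 changes of 0.962 and 0.997 miss a 2-fold minimum, and AT3G12900 at a pseudocount of 1 (log2 change 4.81, adjusted p = 0.077). A pseudocount of 1 or 64 moved the fold of 19 named genes by over 1.5 times. Filters on dim probe sets removed 5 named genes at 40% and 23 at 60%, which are thus untested there. The dimmest 60% filter also lowered the abscisic acid members passing to 2 and the overlap with the authors' deposited table to 172, because fewer probe sets were tested. The 4 enriched lists stayed under an adjusted p of 0.05 with a background of all probe sets of 1 locus, with only part of the unlisted members in the background and with entries taken by locus. The first 2 of these settings can only lower the p of a list, and by locus the counts of the 4 lists did not change. Staying under 0.05 was thus fixed in advance and is no test of the 4 lists. The salicylic acid and anthocyanin lists, which missed it, passed under the first 2 settings (adjusted p = 0.010 to 0.011) and by locus (0.045 and 0.011). By locus only the anthocyanin list changed in its counts, and the salicylic acid list passed through its rank in the adjustment. The count of calls moved most. A 2-fold minimum left 390 (222 higher, 168 lower), by construction. Array weights gave 3779 (2042 higher). Leaving out both arrays numbered 1 gave 1504 (871 higher, 633 lower), with fewer arrays tested. Leaving out 1 array at a time gave 1190 to 2347 calls, 620 to 1362 higher and 560 to 985 lower. It was 1422 without wild type replicate 2, 1190 without mutant replicate 2 and 1197 without mutant replicate 3. In the other alternatives the total was 1687 to 3502, and the cause of the array-weight and block changes was not tested. Camera and fry were not run. Dim probe sets, where intensity is close to 0, carry the least certain folds, and IRT1 ranged from 2.95 to 4.65 on the log2 scale over the alternatives.

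The replicate block gave 1687 calls (910 higher, 777 lower), against 2501 (1334 and 1167) without it, and it changed the call of no named gene. Deviations from the group means of same-numbered arrays correlated at 0.234, 0.0186 and 0.0174 for numbers 1, 2 and 3, so the numbers were not taken to pair the arrays. Only the arrays numbered 1 correlated best with their own number. Wild type replicate 2 correlated best with mutant replicate 3 (0.136), and wild type replicate 3 with mutant replicate 2 (0.169). Whether the arrays pair in that order was not tested, and no fit used it.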

Other observations

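The counts of iron and phosphate members passing without both arrays numbered 1 and at a pseudocount of 64 were tests written before their results were seen. The tests of the shares of a log2 change left, of raw differences, of splits, root markers and peroxidases were chosen after, and the genes in the next paragraph were chosen after their values were seen.

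PYE and BTS, known regulators of the iron response, the zinc transporter gene ZIF1 and the nicotianamine synthase gene NAS2 were higher, and NAS2 went from 256 ± 23.6 to 1155 ± 93 (log2 change 2.11 ± 0.10 SE, n = 3 each). NAS3, of the same family as NAS2, and the zinc transporter gene ZIP3 were lower, with log2 changes of -1.49 ± 0.13 and -1.59 ± 0.09. SWEET13, a sugar transporter gene, rose from 54.2 ± 3.04 to 361 ± 5.77, SUS4 rose by 1.62 ± 0.09 on the log2 scale and PPDK by 1.14 ± 0.10. AT3G49160, of the pyruvate kinase family, fell from 141 ± 10.3 to 28.7 ± 3.61 (log2 change -1.81, and -1.15 at a pseudocount of 64). ACA1 and BCA3, carbonic anhydrase genes, rose by 1.95 ± 0.11 and 1.76 ± 0.16 on the log2 scale, and BCA3, with a wild-type intensity of 34.2 ± 9.5, by 1.14 at a pseudocount of 64 and 2.16 at 1. ESB1 and the peroxidase gene PER64 fell by 1.29 and 1.01 on the log2 scale.

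The real grouping gave 2501 calls and the highest of the other 9 groupings of the 6 arrays gave 0, so 1 of the 10 groupings was as large. The 10 groupings are too few for a share under 0.05. Each of the other 9 also mixes the genotypes within its groups, so a difference between genotypes widens the spread there and lowers the calls. Their 0 is therefore not the level of calls without a difference.

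The 17 named members of the iron and phosphate lists changed together. Without both arrays numbered 1, which deviate together (second principal component, 17.1% of variance), 17 of 17 still passed in the same direction, while calls over all probe sets went from 2501 to 1504. So did 272 of the 274 table probe sets, which were selected for a difference, so the count is weak by itself. The size of the log2 change left without these arrays was 0.957 to 1.11 of the full one (median 1.03). A deviation shared by 1 array of each genotype largely cancels in the difference between genotypes. A share near 1 thus follows from the design and is no test of that deviation as a cause. At a pseudocount of 64, 17 of 17 passed, but so did 274 of 274, so that count does not decide on values near the floor. For the 12 members over an intensity of 100 on every array, the lowest share of the log2 change at a pseudocount of 1 that was left at 64 was 0.810. The size of their change thus depends little on the pseudocount. At intensities over 100 a high share follows by arithmetic, so it is no test of the floor as a cause. For the other 5 (IRT1, BHLH101, bHLH39, MGDC and RNS1) the lowest share was 0.444 and the highest 0.670, so part of the size of their change depends on the pseudocount. The raw values, without any pseudocount, do not settle whether noise near the floor adds to the change. The lowest difference of group means was 173. That is 8.48 times a standard error built on an SD of 25.1. This SD is the 99th percentile within groups among the probe sets with both means at or under 100. The authors' filter asked for a difference over 100, which by itself sets this ratio high. The highest SD among all 21339 groups of 3 arrays with a mean at or under 100 was 70.5, below 173. These spreads describe dim groups only. The mutant groups of the 5 members were brighter, with SD from 5.44 (MGDC) to 114 (IRT1). A difference due to genotype stays open for all 17.

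The root markers CASP1 and TIP2;3 were lower. A smaller share of root tissue in the mutant seedlings may lower both, but 20 of the 22 root markers had no named probe set, so this cannot be told apart from changes within roots. IRT1 and NRT2:1, expressed mainly in roots, were higher, but they are members of the iron and nitrogen lists and were picked from the table. ESB1 and PER64 were lower (log2 changes -1.29 and -1.01). The table was not sorted by root expression, so no balance of higher and lower root genes can be read from these genes.

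Among class III peroxidases in the table, 9 of 10 were lower, against 106 of all 274 table probe sets, and 1 of the 10 is on a shared probe set. Fisher's exact test, adjusted over the 15 families tried, gave p = 0.0157, the one family under 0.05. The families were chosen after the table was read, so a shared peroxidase change is a hypothesis, and a lower root share may also produce it.

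In 50 of the 274 probe sets, an authors' group mean lies outside the range of that group's 3 arrays. An unnamed probe set had intensities of -371.77, -308.19 and -363.99 in wild type and -10.93, -14.97 and 0.18 in the mutant.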
